A study of Caenorhabditis elegans with 4 samples.

How the data were processed

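Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on Caenorhabditis elegans hermaphrodites at L4, the last larval stage, grown at 20 °C. The strain carried a transgene that expresses LIN-39 fused to green fluorescent protein (GFP), and an anti-GFP antibody recovered the DNA bound by the fusion protein. There were 4 libraries, 2 of ChIP DNA and 2 of input DNA (sonicated chromatin set aside before the antibody was added). Per the labels, the 2 libraries of each kind are replicates 1 and 2. Whether these came from separate cultures is not given in the sources used here, so no p-value below measures the spread between cultures. The input libraries entered no comparison of their own.

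The data used were 3 deposited peak lists, 1 for each ChIP replicate and 1 for the series as a whole, here called the series-level list. Per the file headers, the peaks lie on the WormBase WS220 genome build. Per the file headers and their source column, peaks came from the SPP peak caller by way of the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks between replicates. The aligner, the versions, the settings, the IDR threshold and whether reads were pooled for the series-level list are not given in the sources used here. The start and end positions deposited by the authors are 1-based, and every peak of a list has the same width, 496 bp in replicate 1, 490 bp in replicate 2 and 504 bp in the series-level list.

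The score deposited by the authors for each peak is on a log10 scale. Its form was worked out from the values. With n the number in the peak's name, the score equals log10((n - 0.5)/(c + 0.5)), where c came out as a whole number within 0.001 for 99.3% of peaks in replicate 1, 99.6% in replicate 2 and 100% in the series-level list, below the leading block of peaks that share the highest score. This is the form of minus log10 of a false discovery estimate in which c counts peaks called from a background, as SPP obtains by exchanging ChIP and input. No header or label states this, and c is called the recovered background count here. The estimate is 10 raised to minus the score, and a score below 0 means at least as many background calls as peaks. The score carries no count of reads, so the sequencing depth of every library is unknown, and how much of a difference between the replicates comes from depth cannot be measured from the lists.

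The planned ranking was by deposited score. Within the replicate lists, however, the score rose again far down the list: its Spearman correlation with the peak number was 0.884 in replicate 1 and 0.883 in replicate 2, where an order from high to low score would give a negative value. It was -0.992 in the series-level list. Peaks were therefore ranked by peak number, with number 1 read as the strongest, and the ranking by score was run as an alternative. Whether the number is the rank order of the peak caller is not given in the sources used here. Every use of "strongest" or "highest" for replicate peaks rests on that reading, as does any order among series-level peaks of equal score. Peak numbers are ranks within a list and were not read as amounts of binding.

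Overlap between lists meant at least 1 bp in common. Chance was measured by moving one list around each chromosome by a random distance of at least 10000 bp, wrapping at the end. This was done 1000 times per overlap test, and 200 times per rank bin and per correlation. Shift tests were two-sided unless stated otherwise, and the smallest p they can give is 0.001 with 1000 shifts and 0.005 with 200. Chromosome length was taken as the highest peak end in any list. The replicate number given for a series-level peak is the lowest among the replicate peaks that overlap it, and the centre distance is that to the nearest of them, which can be another peak. Under this rule 3 pairs of neighbouring series-level peaks share their replicate numbers and count separately among the 141. Correlations were computed over peaks matched 1 to 1 as mutual nearest centres. The number of series-level peaks on a chromosome was compared with that chromosome's share of the 60000 peaks of the 2 replicate lists, called candidate peaks here, by a two-sided exact binomial test. The test on X was chosen before the data were examined. The tests on the other chromosomes, on the 21 peaks that share the highest score and on position along the autosomes were chosen after. Benjamini-Hochberg adjustment was over the 6 chromosomes. Shares have 95% exact Clopper-Pearson intervals, which cover counting error only. Peaks are positions in the genome and not replicates, so the p-values describe these lists. Of all peaks, 15.2% in replicate 1 and 14.8% in replicate 2 overlapped the next peak of the same list. Exact tests over replicate peaks can therefore count 1 site more than once, and their p-values can be too small. Neighbouring peaks were counted once only in the series-level list.

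A rule for named sites was set before the data were examined. Where no annotation of the same build was at hand, it took the 10 highest-scoring series-level peaks by position. Since 21 peaks shared the highest score, the 10 with the lowest peak numbers were taken, a choice made after. The gene table at hand was for WBcel235, another build, so peaks were not assigned to genes. Positions named outside that rule were chosen after their values were seen. The alternatives were a stricter overlap (50% of the shorter peak, or centres within 100 bp), shorter and longer lists, ranking by score, shifts of 2 to 20 kb, the upper part of each list, the replicate lists in place of the series-level list, expected shares from chromosome length, and neighbouring peaks within 1 kb counted once.

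The shift test and the recovery of background counts were run on simulated data. Simulated positions were drawn evenly along each chromosome, so the crowding of peaks in the real lists was not covered. With 3000 shared sites planted among 30000, the excess over shifted lists came to 3032. With none planted, that run gave an excess of 217 sites with a p of 0.03, a false positive. In a further set of simulations with none planted, 1 of 40 had a p under 0.05 and the mean excess was 14 sites. The simulated background counts were recovered for 100% of peaks. Their scores were built with the same formula, so this checks the computation only and not whether c counts background calls. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.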

Results

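The data describe where the Hox protein LIN-39 was found on the genome of L4 hermaphrodites. LIN-39 patterns the middle of the C. elegans body, including the vulval precursor cells and neurons of the ventral nerve cord. The list of each of the 2 ChIP replicates held exactly 30000 peaks, and the series-level list held 141. Whether 30000 was a preset cut-off is not given in the sources used here. The authors' scores show how far down each list the peaks exceeded a background.

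The strongest LIN-39 sites lay mostly on X. The highest score of the series-level list was shared by 21 peaks, 12 of them on X. Of the 10 with the lowest peak numbers among these, 7 were on X and 1 each on I, II and III. Number 1 of the series-level list was at X 11093894 to 11094397, which was number 2 in replicate 1 and number 1 in replicate 2. The next, at X 13700528 to 13701031, was number 1 in replicate 1 and number 8 in replicate 2. The site at X 9465563 to 9466066 was number 5 in both. X 16681790 to 16682293 was number 4 in replicate 1 and number 6 in replicate 2, and I 4172040 to 4172543 was number 8 and number 7. X 16056220 to 16056723 was number 6 in replicate 1 and number 12 in replicate 2.

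The remaining 4 of these 10 sites stood higher in replicate 2. X 2996845 to 2997348 was number 14 in replicate 1 and number 2 in replicate 2, and X 14525605 to 14526108 was number 15 and number 4. II 10563289 to 10563792 was number 17 in replicate 1 and number 3 in replicate 2. III 7854382 to 7854885 was number 33 in replicate 1, with a score of 0.583, and number 9 in replicate 2. All 10 sites had the highest score of the series-level list (1.61) and of replicate 2 (1.84), and 6 of them had the highest score of replicate 1 (1.28).

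Peaks outnumbered background calls most clearly at the top of each list. The highest score was shared by 10 peaks in replicate 1, 35 in replicate 2 and 21 in the series-level list, and no background call had been recovered at those ranks. Their estimates were 0.0526, 0.0145 and 0.0244. With a count of 0, the estimate depends only on how many peaks share the highest score. A block of 10 peaks cannot give less than 0.0526, so no peak of replicate 1 could have an estimate below 0.05 there, and none had one further down. An estimate below 0.5 was reached by 51 peaks in replicate 1, 156 in replicate 2 and 55 in the series-level list. At number 100, the recovered background count was 88 in replicate 1, 38 in replicate 2 and 109 in the series-level list. The estimate first reached 1 at number 121 in replicate 1, 456 in replicate 2 and 93 in the series-level list. Further down the replicate lists the estimate stayed close to 1 and crossed it again: beyond number 1000 it was below 1 for 8297 peaks of replicate 1 and 1283 of replicate 2, with lowest values of 0.977 and 0.996. At number 10000 the background counts were 10292 and 10652 in replicates 1 and 2. The last 49 of the 141 series-level peaks had scores of 0 or below, with a minimum of -0.185, that is, estimates of 1 or more.

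**Figure D1:**
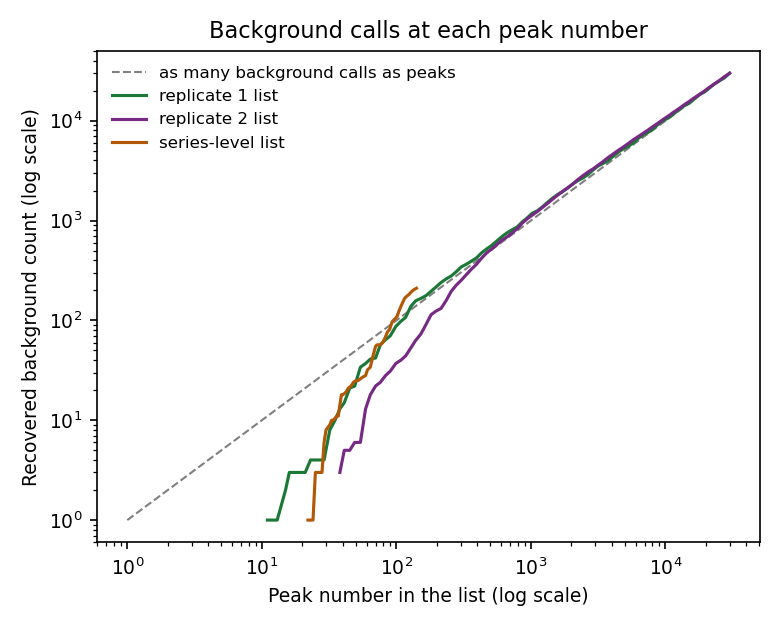
Recovered background count (vertical, log scale) against peak number (horizontal, log scale) for the replicate 1, replicate 2 and series-level lists, with a dashed line where both are equal. The curves start below the line and meet it near number 121 in replicate 1, 456 in replicate 2 and 93 in the series-level list, and ranks with a count of 0 are not drawn.

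The comparison of the replicates asks how many peak positions were found in both. The shared count is the number of replicate 1 peaks that overlapped a replicate 2 peak. It was 5 among the 10 highest peaks of each replicate and 27 among the 50 highest. Among the 1000 highest of each it was 145, against 10.1 ± 3.27 (SD over 1000 shifts) for shifted lists, a 14.4-fold excess (two-sided permutation by shifts, p = 0.001, the smallest the shifts can give). Matched 1 to 1, the 1000 highest of each gave 135 pairs. Ranked by deposited score, the shared count among the 1000 highest was 66.

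Over the full lists, 13597 of the 30000 replicate 1 peaks (45.3%) overlapped a replicate 2 peak, against 26% ± 0.259 (SD) for shifted lists, a 1.75-fold excess (permutation p = 0.001, the smallest the shifts can give). At number 30000 the recovered background counts were 29989 in replicate 1 and 29894 in replicate 2. The 45.3% is therefore a share of candidate peaks and does not measure how many LIN-39 sites were reproduced. The share fell down the list, though not evenly. It was 100% for numbers 1 to 10 of replicate 1, 97.5% for 11 to 50, 70.0% for 201 to 500, 57.9% for 1001 to 2000 and 39.9% for 20001 to 30000, where shifted lists gave 25.9%. Replicate 2 peaks overlapped replicate 1 peaks in 92.0% of cases for numbers 51 to 100, where the share in the other direction was 70.0%, and in 39.1% for numbers 20001 to 30000. Centres of overlapping peaks lay a median of 42.5 bp apart for numbers 11 to 50 of replicate 2 and 130 bp apart for numbers 20001 to 30000, against 229 bp by chance in that last range.

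Over the full lists, peak order was only weakly shared between the replicates. Across the 11683 matched peaks, which are positions and not independent replicates, the Spearman correlation of peak numbers was 0.107, against -0.0024 ± 0.0122 (SD over 200 shifts; two-sided permutation by shifts, p = 0.005, the smallest the shifts can give). Shifted lists matched 6852 peaks on average, so a large part of the 11683 can be chance matches. This correlation therefore does not measure agreement at LIN-39 sites alone. The Pearson correlation of the log10 scores was 0.539, while their Spearman correlation was 0.0527. Within the higher-scoring 15000 of each list, the Spearman correlation of peak numbers was 0.051. With the 1000 highest peaks of each list left out, the Spearman correlation of peak numbers was 0.055 and the Pearson correlation of scores 0.058. Among the 135 matched peaks within the 1000 highest of both, Spearman's correlation was 0.470, which did not pass the same permutation test (p = 0.124). That test cannot decide here, since shifted lists matched only 9.85 peaks on average and their correlations varied widely (SD 0.358).

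The series-level list was set against the replicates to see how it relates to them. All 141 series-level peaks overlapped a peak in both replicate lists. The IDR procedure compares peaks between replicates, so this is largely built into the list, and no test was drawn from it. With centres within 100 bp required in both, 117 remained. The median number of all 141 peaks was 198 in replicate 1 and 86 in replicate 2. The 1000 highest peaks held 112 of the 141 in replicate 1, 131 in replicate 2 and 102 in both, and every one of the 141 was within the 1000 highest of at least 1 replicate. Of the 141, 57 stood closer to the top in replicate 1, 83 in replicate 2, and 1 had the same number in both.

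Some series-level sites ranked very differently in the replicates. I 10031663 to 10032166 was number 20 in replicate 2 and number 18261 in replicate 1. I 16774 to 17277, near the left end of the chromosome, was number 46 in replicate 2 and number 12398 in replicate 1. In the other direction, IV 8492699 to 8493202 was number 31 in replicate 1 and number 18568 in replicate 2. X 1389333 to 1389836 was number 14 in replicate 2 and number 1340 in replicate 1. Beyond number 1000 in replicate 1 only were 29 series-level peaks, and beyond it in replicate 2 only were 10. Conversely, the 50 highest peaks of replicate 1 included 44 that overlapped a series-level peak, and the 50 highest of replicate 2 included 48.

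**Figure D2:**
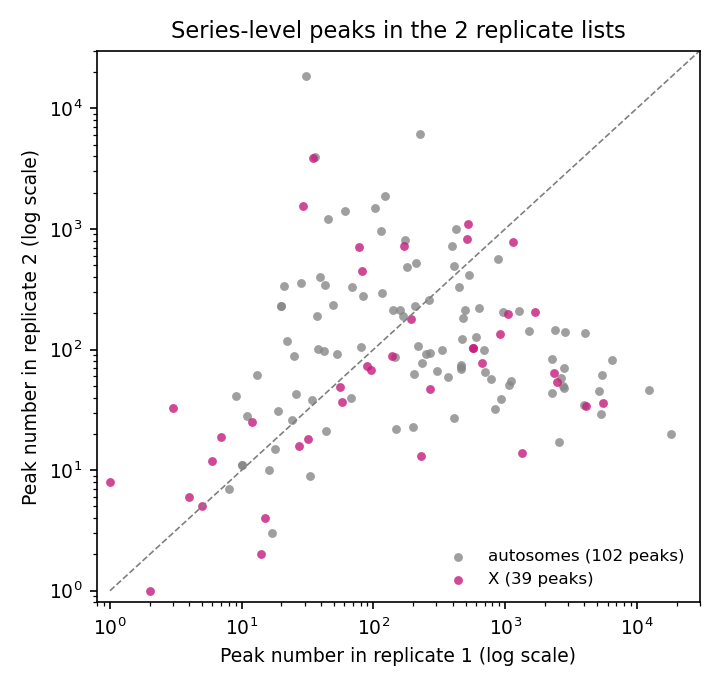
Peak number of each of the 141 series-level peaks in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), with the 39 peaks on X in magenta, the 102 autosomal peaks in grey and a dashed line where both numbers are equal. The points spread widely around the line, and 29 peaks lie beyond number 1000 in replicate 1 only.

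The series-level sites were unevenly spread over the chromosomes. X held 39 of the 141 peaks (27.7%, 95% interval 20.5 to 35.8) against 20.6% of the candidate peaks (two-sided exact binomial test, p = 0.0471; adjusted p = 0.0706 over the 6 chromosomes). V held 12 (8.51%, 4.48 to 14.4) against 20.9% (exact p = 1.08e-04; adjusted p = 6.48e-04). I held 31 (22%, 15.5 to 29.7) against 14.3%, and III held 28 (19.9%, 13.6 to 27.4) against 12.4%, each with an adjusted p of 0.0304. II held 13 (9.22%) and IV held 18 (12.8%), and neither differed from its share of candidate peaks by the exact test (adjusted p = 0.111 and 0.181).

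The excess on X was largest in the strongest sites. Of the 21 series-level peaks with the highest score, 12 were on X (57.1%, 34 to 78.2; exact binomial p = 2.59e-04; adjusted p = 0.00156). Of the other 120, 27 were on X (22.5%, 15.4 to 31.0; exact p = 0.574), and the odds of lying on X differed between these sets 4.59-fold (two-sided Fisher's exact test, p = 0.00258). The 21 highest peaks of replicate 1 included 10 on X (exact p = 0.00508) and those of replicate 2 included 12 (exact p = 2.59e-04). Smaller excesses were seen further down: at numbers 501 to 1000 X held 25% in replicate 1 (exact p = 0.0173) and 25.6% in replicate 2 (exact p = 0.00669), and in replicate 2 it held 26.3% at numbers 201 to 500 (exact p = 0.0182) and 22.4% at 1001 to 5000 (exact p = 0.00583), with no adjustment for the number of ranges. Other ranges lay lower, with 13.8% at numbers 22 to 50 of replicate 1 (exact p = 0.493) and 19.1% at numbers 20001 to 30000 of replicate 2 (exact p = 2.77e-04). At number 500 the recovered background counts were 553 in replicate 1 and 509 in replicate 2. Whether the shares beyond that number reflect LIN-39 sites or background positions cannot be told from the lists. Over all peaks beyond number 1000, X held 20.65% of the peaks in replicate 1 and 20.21% in replicate 2. These peaks make up most of the candidate peaks, so closeness to the candidate share is built in and shows no loss of an excess. X held 17.7% of the chromosome spans. Among the other 120 peaks, 29 were on I and 26 on III (exact test, adjusted p = 0.00988 each), and V held 11 of these 120 (adjusted p = 0.00602). I and III held 2 each of the 21, and no test compared these sets for chromosomes other than X.

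These shares depended on the list used. At number 1000 of the replicate lists, recovered background calls outnumbered the peaks (1164 in replicate 1 and 1109 in replicate 2). Shares over the 1000 highest peaks may therefore describe background positions as well as LIN-39 sites. For X the test also passed over the 1000 highest peaks of replicate 1 (24.7%, exact p = 0.00174) and replicate 2 (26%, exact p = 3.91e-05), the 141 highest of replicate 2 (28.4%, exact p = 0.0282), the upper 70 series-level peaks (31.4%, exact p = 0.0369) and with shares expected from chromosome spans (exact p = 0.00379). It no longer passed with neighbouring peaks within 1 kb counted once (27.5%, exact p = 0.0572), over the 141 highest peaks of replicate 1 (25.5%, exact p = 0.146), or over the 1000 highest peaks by deposited score (21% in replicate 1 and 21.8% in replicate 2). The low share of V was seen in the 141 highest peaks of replicate 2 (9.22%, exact p = 2.66e-04), while those of replicate 1 gave 16.3% (exact p = 0.214) and the 1000 highest gave 20.5% in replicate 1 and 18.4% in replicate 2. The share of I was 22% in the 141 highest peaks of replicate 1 (exact p = 0.0152) and 19.1% in those of replicate 2 (exact p = 0.116), and 16% and 14.8% in the 1000 highest of replicates 1 and 2 (exact p = 0.124 and 0.619). By deposited score, the 1000 highest gave 15.9% on I in replicate 1 (exact p = 0.148) and 16.5% in replicate 2 (exact p = 0.0465). In the upper 70 series-level peaks the share of I was 22.9% (exact p = 0.0572). For III, the 141 highest peaks gave 10.6% in replicate 1 and 13.5% in replicate 2, against 12.4% of the candidate peaks, so its excess did not pass in these, nor in the upper 70 series-level peaks (18.6%, exact p = 0.143).

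**Figure D3:**
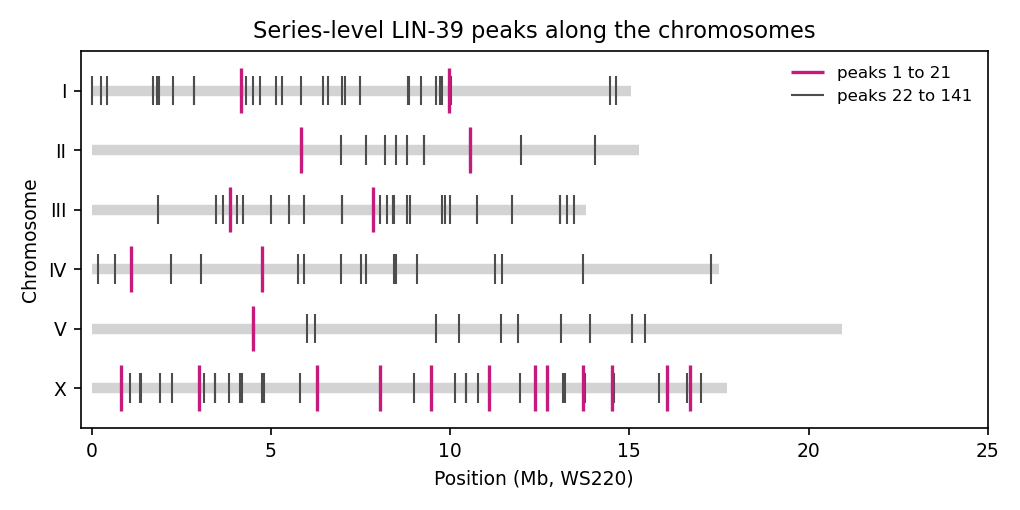
Positions of the 141 series-level LIN-39 peaks (horizontal axis in Mb, WS220) on the 6 chromosomes (vertical axis), with the 21 peaks that share the highest score as tall magenta lines and the others as short dark lines. Of the 21, 12 lie on X, while V carries 12 peaks in all.

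**Figure D4:**
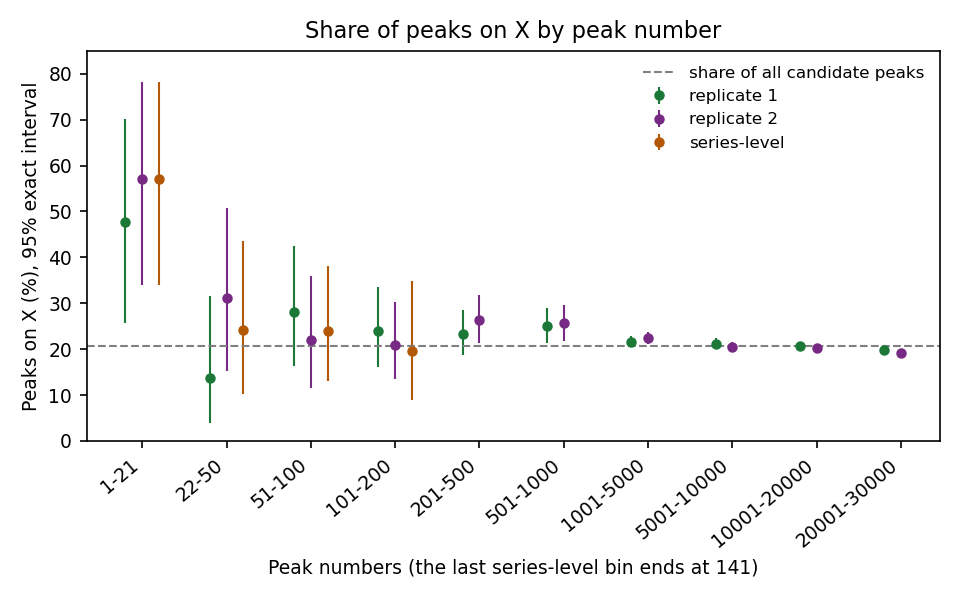
Share of peaks on X in percent (vertical) by range of peak numbers (horizontal) for the replicate 1, replicate 2 and series-level lists, with 95% exact intervals as bars and the 20.6% share of all candidate peaks as a dashed line. The share is 47.6% to 57.1% for numbers 1 to 21. It is near the line in the ranges beyond number 1000, which hold most of the candidate peaks that set the line.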

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

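Of 69 alternatives to 10 results, 41 kept the direction and the side of the 0.05 threshold, 22 kept the direction but no longer passed, 4 moved a count by more than 1.5 times and 2 turned the direction. Chosen after seeing the data were the peak-number ranking, shifts of 2 to 20 kb, the 138 merged sites, the 141 highest replicate peaks, expected shares from chromosome spans, the correlation with and without the highest 1000, and every test on V, I, III, the 21 strongest peaks and the central part of the autosomes. The overlap of the full lists passed under every alternative run, with shares of 21.3% to 45.3%. The presence of series-level peaks in both replicates (117 to 141 peaks) is largely built in by IDR, so its 4 alternatives among the 41 say little about stability. The shared count among the highest peaks was 145 at a list length of 1000, 92 at 500, 275 at 2000, 88 with centres within 100 bp and 66 by deposited score, each above chance; the list lengths and the stricter overlap change the count by construction, and the cause was not tested for the score. The correlation of 0.107 became 0.0527 with scores in place of peak numbers, still past the threshold. It was 0.470 in the highest 1000, where the test did not pass but cannot decide because few shifted peaks match. This case is counted among the 22 although the correlation was higher. The X share of 27.7% became 27.5% with merged sites and 25.5% in the 141 highest of replicate 1, and 21% and 21.8% in the 1000 highest of replicates 1 and 2 by score, none of which passed. V, at 8.51%, rose to 16.3% in the 141 highest of replicate 1, to 19.7% and 19.3% in the 1000 highest of replicates 1 and 2 by score, and to between 18.4% and 20.5% in the 1000 highest of 1 replicate by number, where the list length changes along with the replicate left out (the 141 highest of replicate 2 gave 9.22%). The central part of the autosomes fell from 52.0% to 45.8% in the upper 70 peaks and 47.6% in the 141 highest of replicate 1, and passed in neither. III turned from 19.9% to below its expected 12.4% in replicate 1, at 10.6% in the 141 highest (exact p = 0.61) and 12.3% in the 1000 highest by score. Neither of these shares differed from the expected one by the exact test, so they show a lost excess and not a deficit. The cause was not tested for the shares. No paired analysis was possible because the input libraries have no values among the lists used here and no comparison sets ChIP against input by replicate number. The planned results on gene starts, gene lists and the Hox-Pbx word, with all their alternatives, were not run, since the gene table is for another build, and shares expected from true chromosome length were replaced by shares of candidate peaks for the same reason. Unknown sequencing depth limits every comparison of the replicates.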

Other observations

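The tests in this part were chosen only after the results were seen. Series-level peaks on the autosomes lay in chromosome centres more often than candidate peaks did. In C. elegans these centres hold more of the conserved genes than the arms do, but a link to genes was not tested. With each chromosome split into 3 equal parts, 53 of the 102 autosomal series-level peaks lay in the central part (52.0%, 95% interval 41.8 to 62), against 38.2% of the candidate peaks (two-sided exact binomial test, p = 0.00566). The share exceeded that of the candidate peaks on all 5 autosomes, from 46.4% on III to 69.2% on II. The 1000 highest peaks gave 47.1% in replicate 1 (exact p = 5.70e-07) and 47.7% in replicate 2 (exact p = 1.34e-07), while the upper 70 series-level peaks gave 45.8% (exact p = 0.299) and the 141 highest peaks of replicate 1 gave 47.6% (exact p = 0.0558), neither of which passed. Recovered background calls outnumbered peaks at number 1000 (1164 in replicate 1 and 1109 in replicate 2). A central excess of background positions therefore cannot be told apart from one of LIN-39 sites there. On X, 9 of 39 series-level peaks lay in the central part (23.1%, 11.1 to 39.3), against 35.8% of its candidate peaks (exact p = 0.132). The odds differed 3.6-fold between autosomes and X (two-sided Fisher's exact test, p = 0.00231).

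No clustering of series-level sites beyond the density of candidate peaks was detectable. After peaks within 1 kb were counted once, 138 sites remained, and 7 neighbouring pairs lay within 20 kb of each other, against 4.39 ± 2.07 (SD) in 1000 random draws from the candidate peaks (two-sided permutation p = 0.22). Within 50 kb there were 11 pairs, against 11 ± 2.99. One pair joined the site at II 10563289 to 10563792, number 6 of the series-level list, to a site at II 10558701 to 10559204, number 84, which starts 4588 bp away.

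A few high-ranking replicate peaks overlapped no series-level peak, and some of these overlapped no peak of the other replicate. X 13514267 to 13514756, number 30 in replicate 2 with that list's highest score of 1.84, overlapped no peak of replicate 1 and no series-level peak, and the same held for III 12612427 to 12612916, number 42 in replicate 2. In replicate 1, I 1883667 to 1884162, number 41 with a score of 0.417, overlapped no peak of replicate 2. The recovered background count at that rank was 15. The highest replicate 1 peak outside the series-level list was number 30, at V 19973627 to 19974122, whose overlapping replicate 2 peak was number 25212.

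X held more of the strongest LIN-39 peaks than of the candidate peaks, 12 of 21 in the series-level list. One X site split into several peaks would not give this, because the closest X peaks among the 21 started 327366 bp apart. Nor did it rest on a single ChIP library, as the larger of the exact binomial p-values of the replicates alone was 0.00508. As a hypothesis, the strongest LIN-39 binding may favour sites on X. Positions on X that give strong peaks in any anti-GFP ChIP stay open as an untested account, since no other GFP-tagged protein was analysed here.

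The series-level list followed replicate 2 more closely than replicate 1, with 29 peaks within number 1000 in replicate 2 and beyond it in replicate 1. Chance overlap with unrelated replicate 1 peaks stays open: for these 29 sites the centres of both replicates lay a median of 53 bp apart, against 229 bp in shifted lists (one-sided permutation by shifts, p = 0.011), but the sites had been selected by comparing the replicates and the shifted lists had not. A lower yield of enriched fragments in replicate 1 could leave real sites far down its list, and 29 against 10 sites in the other direction differed from an even split (two-sided exact binomial test, p = 0.00338). This cannot be told apart from a series-level list that was itself drawn more from replicate 2, since how the replicates were combined is not given in the sources used here. No biological explanation was tested.

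The replicates shared more positions than shifted lists beyond number 1000, where background calls were about as many as peaks. Peaks crowding into the same regions would not account for it at the scale tested: leaving out the 1000 highest peaks of each, 43.1% of replicate 1 peaks overlapped a replicate 2 peak, 1.64 times the 26.4% given by shifts of 2 to 20 kb (two-sided permutation by shifts, p = 0.001, the smallest the shifts can give). Background positions common to both ChIP libraries, such as open chromatin or sequence that maps unevenly, could give the same excess and cannot be told apart from weak binding, since the lists hold the number of background calls (1.03 per peak at the lowest of numbers 1000, 2000, 5000 and 10000 in either replicate) and not their positions. The input libraries, which would show those positions, were not analysed here.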
